A study of Mus musculus with 768 samples.

How the data were processed

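Single-cell RNA profiles of the mouse mammary gland were analysed from 2 plates of 384 wells, 1 plate per genotype, with 1 sorted cell per well. The deposited values are raw read counts per gene and cell, which the authors made from Smart-Seq2 libraries sequenced on a HiSeq2500. Per the submitters' processing notes the reads were aligned with STAR to mm10. The versions, the counting tool, the gene annotation and the use of strand are not given in the sources used here. The libraries carry no unique molecular identifiers. The files held 24490 rows. The 492 rows with a repeated gene name were added to the row of the same name, and the eGFP row was set apart, which left 23997 names. All values were whole numbers, and every column was joined to its label by plate and well.

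Cells with at least 50000 reads and 1000 detected genes were kept, 334 of the control and 283 of the N1ICD-EGFP plate. No filter on mitochondrial reads was applied, since the files hold no mitochondrial rows. No doublets were called, since single cells were sorted into wells, and an alternative left out cells whose number of genes exceeded the plate median by 3 median absolute deviations. The wells left out held a median of 28772 reads in the control plate (50 wells) and 665 reads in the N1ICD-EGFP plate (101 wells). Reads of the kept cells were summed by plate and scaled to the same total (CPM). Ratios are log2 ratios of CPM plus a pseudocount of 1, and folds are plain ratios of CPM. A fold against 0 reads used a floor of 3 counts over the group. Shares of cells with a read were taken after thinning each cell to 50000 reads without replacement, and also without thinning. Sums have exact Poisson 95% intervals and shares Clopper-Pearson intervals, both for counting error only. Gene coordinates are from the RefSeq table for GRCm38.p6, the assembly behind mm10.

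The labels name no animal, so each plate was taken as 1 sample and no p-values or counts of changed genes were computed. 23 gene lists and the markers of 7 cell classes were fixed before the data were examined, and 3 list genes were not in the files. The lists cover Notch targets, Notch machinery, hormone-sensing, luminal progenitor, milk protein, basal, pan-luminal, milk lipid, prolactin and STAT5, involution, S phase, G2 and M phase, Wnt, immediate early, interferon, MHC, p53, mesenchymal, immune, fibroblast, endothelial, adipocyte and red blood cell genes. A list was summarised by the median log2 ratio of its members at 5 CPM or more in either group. That median was placed as a percentile among 10000 random lists, each member drawn from the 100 genes nearest in mean expression.

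The genes named in the text follow a rule fixed before the data were examined. Over all cells it takes the 14 highest and 14 lowest log2 ratios among genes at 20 CPM or more, read in at least 20% of the cells of the higher group, with the same direction in the mean of per-cell CPM, in the share of cells and in all 4 comparisons between well columns 1 to 12 and 13 to 24 of the plates. Within a class it takes 6 and 6 without the condition on well columns. Predicted, ribosomal protein and reporter genes are left out. Up to 3 members of each list in each direction and 14 fixed genes are added. The further condition that a list member be read in at least 20% of cells was set after low-coverage members had been seen to turn round between settings. Without it the added genes number 114 over all cells, of which 79 kept their direction in every setting and 41 stayed past 1.5 times, with 29 reversed values. Within luminal progenitor/secretory-like cells they number 103, of which 70 kept their direction and 30 stayed past 1.5 times, with 34 reversed values.

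Each plate was clustered on its own with the Leiden method (2000 variable genes, 15 principal components, 15 neighbours, resolution 0.8, seed 0) on CPM divided by 100 and log-transformed. A cluster was named after the class with the most raised markers, if at least 3, where a raised marker was read in at least 20% of its cells and lay 1 log2 unit or more above the mean over clusters. Clusters stayed unnamed with fewer markers, when shallow with no marker of the class among their 10 leading genes, or with more markers of another class there. Progenitor and secretory markers were raised together, so both were joined in 1 luminal progenitor/secretory-like class of 206 control and 183 N1ICD-EGFP cells. This joint class, and this naming rule, were set after the data had been seen. Classes of at least 20 cells in both plates were compared. The class markers overlap with the hormone-sensing, luminal progenitor and milk protein lists.

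Alternatives covered stricter and looser cell filters, possible doublets, scaling, thinning, pseudocount, well columns, list membership and clustering. The procedure was tested on simulated data with 11222 genes. Both simulated groups were drawn from the means and spread of control cells, without a plate difference. The simulated changes were increases and decreases. Of genes at 20 CPM or more, 88.2% of 85 changed 2-fold and 100% of 72 changed 4-fold were recovered past 1.5 times. At this level 8.90% of 7982 unchanged genes also passed 1.5 times. Of genes at 5 to 20 CPM, 33.6% of 3040 unchanged genes passed it. A list of 12 doubled genes lay at percentile 100 and an unchanged list at 29.2. Tools were Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, scanpy 1.11.5, igraph 0.11.9 and matplotlib 3.10.9.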

Results

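Single cells of the mouse mammary gland were profiled by Smart-Seq2, a full-length protocol in which each sorted cell is a library of its own. All animals carried WAP-CRE, a Cre recombinase under the promoter of the milk gene Wap, which is used in the alveolar luminal cells of pregnancy and lactation. In the control group Cre switched on the red reporter tdTomato from the Rosa26 locus. In the other group it switched on N1ICD, the intracellular and constitutively active part of the receptor Notch1, together with the green reporter EGFP. The mice were of the C57BL/6 strain, and inguinal glands were taken after what the labels call a lactation of 3 to 4 months. Reporter-positive cells were sorted into 384 wells per plate, with 1 plate per genotype. The comparison asks how active Notch1 changes the luminal cells in which WAP-CRE had acted.

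Of the 384 wells of each plate, 86.98% in the control (Clopper-Pearson interval 83.2 to 90.2) and 73.7% in the N1ICD-EGFP plate (68.99 to 78.03) held a cell with at least 50000 reads and 1000 genes. The kept cells held 50048 to 608476 reads in the control plate (median 241888) and 51736 to 615615 in the N1ICD-EGFP plate (median 348469). Despite the greater depth, fewer genes were detected per N1ICD-EGFP cell, with a median of 2482 against 3598 in the control and 2088 against 3107.5 once every cell was thinned to 50000 reads. No animal is named in the labels, so each group counts as 1 sample, no difference has a replicate check, and genotype, plate and reporter colour cannot be told apart. Intervals are exact 95% intervals and cover counting error only, because PCR reads without molecular identifiers are not independent molecules. Percentiles of gene lists describe these 2 libraries, and higher and lower refer to size alone.

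Notch1 itself (chromosome 2, 26457902 to 26503822, GRCm38, the mm10 build; protein-coding) was read at 197.6 CPM (reads scaled to the same total in both groups, 194.5 to 200.7) in the summed control cells and at 225.04 CPM (222.1 to 228.04) in the N1ICD-EGFP cells, a log2 ratio of 0.19. After thinning it was read in 68.6% and 65.4% of cells, against 74.6% and 71.02% unthinned. Reads of the transgene, which holds part of the Notch1 sequence, cannot be told from those of the endogenous gene in a gene count. The eGFP row separated the plates: 3095 reads in 93 N1ICD-EGFP cells (32.9%, 27.4 to 38.7), or 31.8 CPM, against 64 reads in 55 control cells (16.5%, 12.7 to 20.9), or 0.791 CPM. No control cell held more than 2 eGFP reads, whereas 81 N1ICD-EGFP cells held 5 or more, so the control share is the background of this row at median depths of 241888 and 348469 reads.

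Genes of the hormone-sensing luminal lineage were far lower in the N1ICD-EGFP plate. The prolactin receptor Prlr (chromosome 15, 10177238 to 10349190) was 14.9-fold lower, at 177.6 against 2649.98 CPM. The pioneer factor Foxa1 was 10.04-fold lower (109.5 to 10.9 CPM), the Wnt ligand Wnt4 9.18-fold (103.7 to 11.3), the progesterone receptor Pgr 7.18-fold (122.3 to 17.03) and the estrogen receptor Esr1 5.95-fold (25.1 to 4.21). Of the 12 measured members of the hormone-sensing list 9 were at least 1.5 times lower and none was 1.5 times higher, with a median log2 ratio of -2.55, below all 10000 random lists matched on expression. These sums over all cells also carry the shares of the cell classes. Within luminal progenitor/secretory-like cells Prlr was 2.73-fold lower (125.5 to 45.9 CPM). The list median there was -0.88 (5 of 9 members lower, 1 higher), and it turned round in some settings. The genes with the lowest ratios in the whole comparison included the choline transporter Slc5a7 (chromosome 17, 54273590 to 54299038), with 7927 reads in the control and 5 in the N1ICD-EGFP plate, the mechanosensitive channel Piezo2, and Hepacam2, Iigp1, Cxcl15, Slc7a2, Ido1, Tmem56, Agtr1a, Mtmr7, Gipc2, Slco2a1 and Tgm2. Of these, Ido1, the enzyme that opens tryptophan breakdown to kynurenine, went from 769.6 to 53.7 CPM, the angiotensin receptor Agtr1a from 501 to 43.1, and the transglutaminase Tgm2 from 1422 to 152.1. Ido1 and Cxcl15 were leading genes of the hormone-sensing luminal-like cluster in both plates, and Agtr1a and Tmem56 in that of the N1ICD-EGFP plate. Their sums also carry the share of this class, 19.5% of control and 2.47% of N1ICD-EGFP cells.

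Milk genes were lower as well. The caseins Csn1s1, Csn1s2a and Csn2 stood at 7495, 937 and 1891 CPM in the control plate and at 1590.1, 152.8 and 710.3 CPM in the N1ICD-EGFP plate, and 7 of 8 measured members of the milk protein list were at least 1.5 times lower (median log2 ratio -1.64, percentile 0). Wap, whose promoter drives the Cre, was near the floor in both plates (2.31 and 0.544 CPM). The prolactin and STAT5 list had 6 of 8 members at least 1.5 times lower (median -0.88, percentile 0.0200), among them Stat5a, the transcription factor downstream of the prolactin receptor, at 183.9 and 85.7 CPM. Of the luminal progenitor list, Ltf (lactoferrin) was 5.71-fold lower (8929 to 1565 CPM) and Aldh1a3 2.30-fold, but Kit, a receptor of luminal progenitors, differed by less than 1.5 times (474 and 626 CPM); the list median was -0.45 (percentile 0.850). Elf5, the transcription factor of the alveolar lineage, stood at 172.8 and 122.7 CPM. Milk lipid genes went both ways, 4 higher and 5 lower of 17, with Fasn 2.197-fold and Dgat2 6.96-fold lower and a median of -0.17 (percentile 7.96).

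Notch target genes were higher. Hes1 (chromosome 16, 30065357 to 30067796), a transcriptional repressor directly downstream of Notch, was 2.73-fold higher (180.9 to 494 CPM), and the feedback regulator Nrarp 3.06-fold (21.6 to 65.97 CPM). Hey1, another target of the family, was 1.64-fold lower (385 to 234.7 CPM), a ratio under 1.5 times in 3 settings, which were well columns 1 to 12 (log2 -0.48), cells other than immune-like (-0.53) and cells outside unnamed clusters (-0.52). Heyl was read in few cells of either plate (0.299% and 2.83%, thinned; 0.299% and 3.18% unthinned), and its log2 ratio of 2.26 was 0.26 by the mean of per-cell CPM and 0.17 when thinned before summing. Of 10 measured members 7 were at least 1.5 times higher and 1 lower, with a median of 0.997 (percentile 99.99; middle 95% of random lists -0.41 to 0.58). Among receptors, ligands and machinery, Notch2 was 3.27-fold higher over all cells (64.3 to 210.2 CPM), but 1.78-fold within luminal progenitor/secretory-like cells, where its log2 ratio was 0.47 in well columns 1 to 12. Of the list, 4 of 21 members were higher, 4 lower and the median was 0.17 (percentile 77).

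The highest ratios belonged to Lect1 (chondromodulin, a secreted inhibitor of vessel growth), with 0.988 CPM in the control and 451 in the N1ICD-EGFP plate, and to the lipoxygenase Alox15 (53.7 to 1066 CPM, 19.9-fold). Alox12e, another lipoxygenase near it on chromosome 11, was 5.50-fold higher (296.2 to 1629 CPM). Lect1 was read in 1.497% of control and 28.6% of N1ICD-EGFP cells after thinning (1.497% and 35.3% unthinned). Palmd was 10.3-fold higher, the matrix genes Fbn2 and Spon1 6.88-fold and 4.25-fold, the transcription factor Foxc1 4.71-fold, the nuclear body protein Sp100 5.04-fold, the lectin Lgals4 4.29-fold and haptoglobin, Hp, 3.84-fold (949 to 3644 CPM). Cd163, a scavenger receptor of macrophages, Arhgdib, a gene of blood cells, and the MHC class II genes H2-Ab1 and H2-Eb1 were 6.94-fold, 4.26-fold, 4.30-fold and 4.09-fold higher, and immune cell markers were higher beside them (11 of 14 members, median 1.48, percentile 100). Without immune-like cells the log2 ratio of H2-Eb1 went from 2.03 to 0.46, under 1.5 times, whereas Cd163, Arhgdib and H2-Ab1 stayed past 1.5 times higher.

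**Figure D1:**
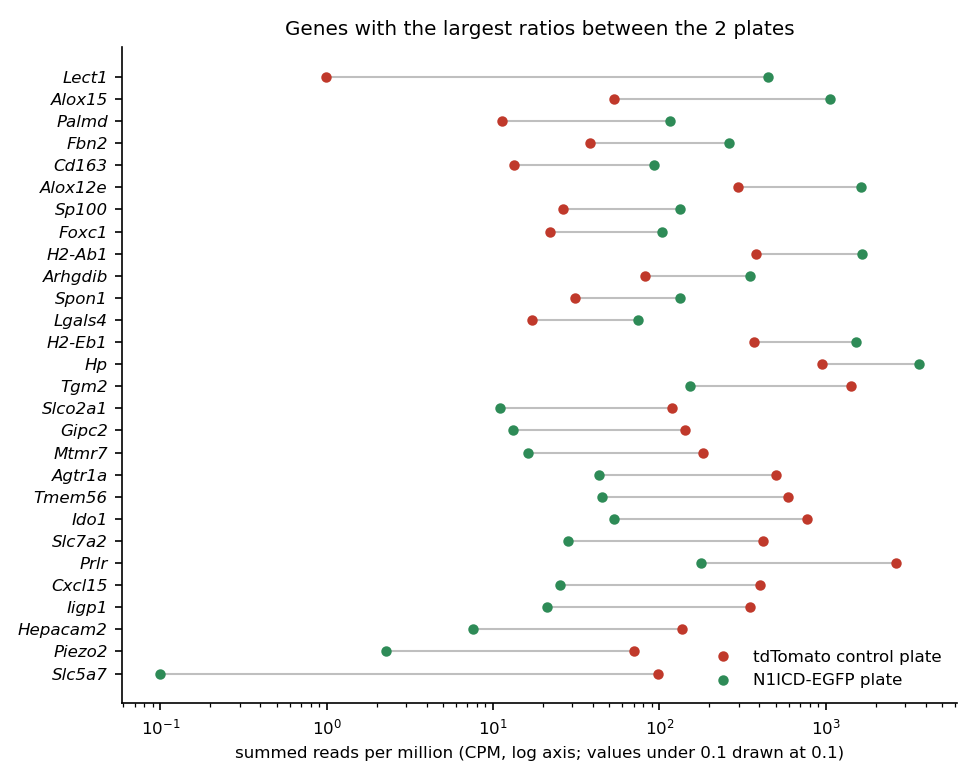
Summed reads scaled to the same total (CPM, log axis) of the 28 genes with the largest ratios that met the fixed rule, in the tdTomato control plate (red points) and the N1ICD-EGFP plate (green points), joined by a grey line for each gene; values under 0.1 are drawn at 0.1. Lect1 stood at 0.988 and 451 CPM and Slc5a7 at 97.9 and 0.0514 CPM, at opposite ends of the plot.

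S phase genes were higher in 9 of 17 members (median 0.75, percentile 99.9), a median under 1.5 times in 5 settings, the lowest being 0.24 outside unnamed clusters, 0.48 without possible doublets and 0.54 without immune-like cells. G2 and M phase genes were higher in 10 of 14 (median 2.11, percentile 100), a median that was -0.22 in well columns 13 to 24 and 0.33 outside unnamed clusters. Basal and myoepithelial markers were lower in 7 and higher in 2 of 11 (median -0.78, percentile 0.0700), with a median of 0.29 in well columns 13 to 24, -0.28 when thinned before summing, -0.42 by the mean of per-cell CPM and -0.53 under the stricter filter. Interferon response genes had a median of 0.97 (percentile 100; 9 of 14 higher) that became -0.082 without immune-like cells, and MHC genes one of 0.77 (percentile 99.96; 7 of 11 higher) that became 0.32 and, in well columns 1 to 12, 0.56. Mesenchymal transition genes were higher in 5 and lower in 3 of 8 (median 1.13, percentile 99.94) and fibroblast markers higher in 5 and lower in 2 of 9 (0.67, 98.96). Endothelial and pericyte markers were higher in 6 of 7 (0.9996, 95.8), with a median inside the middle 95% of random lists (-0.60 to 1.18). The mesenchymal median was 0.41 with members at 1 CPM or more, the endothelial one 0.49 in well columns 1 to 12, and the fibroblast one 0.17 there, 0.51 without possible doublets and -0.62 outside unnamed clusters. Cell cycle inhibitor, p53 and senescence genes had a median of 0.47 (percentile 96.8). Medians lay nearer 0 for pan-luminal keratins and junction genes (-0.092, percentile 19.6), involution and STAT3 genes (-0.0017, 39.2), Wnt pathway genes (0.049, 50.1) and dissociation and immediate early genes (0.20, 88.4). Adipocyte and red blood cell lists each had 1 measured member (0.81, percentile 87.7, and 0.38, 67.8), and the adipocyte value was -0.66 in well columns 1 to 12, -0.47 under the stricter filter, -0.37 when thinned before summing and 0.38 with members at 1 CPM or more. The median over all 12021 genes at 5 CPM or more was 0.07.

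**Figure D2:**
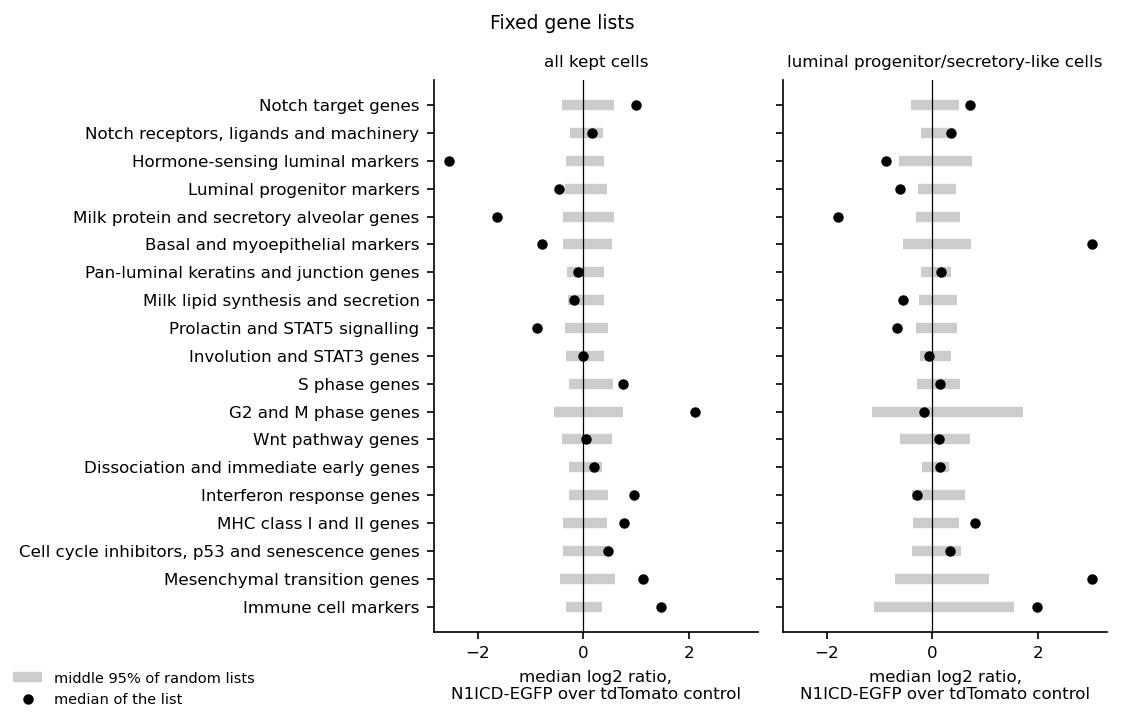
Median log2 ratio (N1ICD-EGFP over tdTomato control) of each fixed gene list with at least 5 measured members in both panels, over all kept cells (left) and over luminal progenitor/secretory-like cells (right). Black points are list medians and grey bars the middle 95% of 10000 random lists matched on expression; over all kept cells the hormone-sensing median of -2.55 lay left of its bar and the Notch target median of 0.997 right of it.

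Clustering each plate on its own gave classes in unequal shares, with a basal-like cluster in the control plate alone. Hormone-sensing luminal-like cells were 65 in the control plate (19.5%, 15.4 to 24.1; cluster 3) and 7 in the N1ICD-EGFP plate (2.47%, 1.0001 to 5.03; cluster 7). Luminal progenitor/secretory-like cells, in which markers of luminal progenitors and of secretory alveolar cells were raised together, were 61.7% (56.2 to 66.9) and 64.7% (58.8 to 70.2). Immune-like cells were 24 (7.19%, 4.66 to 10.5) and 48 (16.96%, 12.8 to 21.9), the latter in clusters led by genes of B cells (Cd79a, Ms4a1; 25 cells), T cells (Cd3g; 8 cells) and macrophages (C1qb, Retnla, Lyz2; 15 cells). Basal-like cells were 7 (2.096%, 0.847 to 4.27) and 0 (0 to 1.295), where a floor of 3 counts allows a share of up to 1.06%, but 2 (0.707%) in the N1ICD-EGFP plate with both plates clustered together. Of the 7 control cells 6 lay in well columns 1 to 12 (3.43% of the cells there, against 0.629% in columns 13 to 24). Unnamed clusters held 32 cells (9.58%) and 45 cells (15.9%), the control one shallow at a median of 72400 reads. The hormone-sensing counts stayed at 65 and 7 at both other clustering resolutions and with both plates clustered together, but were 31 (10.5%) and 0 without possible doublets and 64 and 28 (9.89%) when clustered on the fixed markers alone. Possible doublets are cells with many genes, and hormone-sensing luminal-like cells had the most, with medians of 5400 (control) and 4279 (N1ICD-EGFP). The plate medians were 3598 and 2482, so that setting can take out cells of this class that are not doublets. Without possible doublets the luminal progenitor/secretory-like share was 67.7% in the control and 41.02% in the N1ICD-EGFP plate, and in well columns 13 to 24 the hormone-sensing share of the N1ICD-EGFP plate was 0.719%. At the lowest resolution the control plate kept no unnamed cluster, and its immune-like share was 17.4%, above the 16.96% of the other plate. Under the stricter filter the control immune-like share was 2.79% against 9.84%. Which cells the sorting gates passed can set any of these shares.

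**Figure D3:**
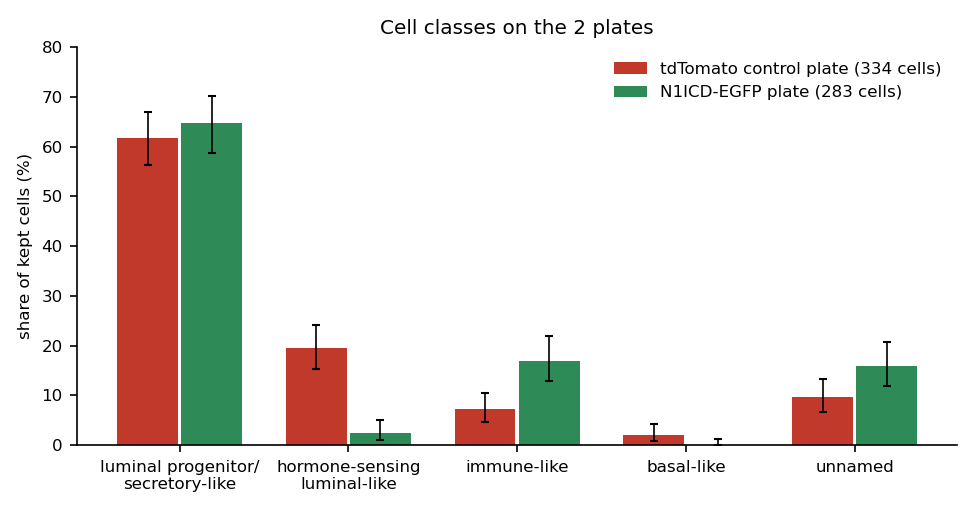
Share of kept cells (%) in each class on the tdTomato control plate (red bars) and the N1ICD-EGFP plate (green bars), with exact Clopper-Pearson 95% intervals as error bars. Hormone-sensing luminal-like cells were 19.5% and 2.47%, and immune-like cells 7.19% and 16.96%.

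Within the luminal progenitor/secretory-like cells (clusters 0, 1 and 2 of the control and 0, 2 and 6 of the N1ICD-EGFP plate), Notch1 stood at 276.7 and 279.5 CPM, while Hes1 was 2.84-fold higher (227.8 to 646 CPM), Nrarp 2.69-fold higher and Hey1 1.70-fold lower (609 to 358.7 CPM; log2 -0.53 with both plates clustered together). Of the Notch target list 4 of 8 members were at least 1.5 times higher and 1 lower (median 0.71, percentile 99.8). Slc5a7 was read 7364 times in the control cells and 0 times in the N1ICD-EGFP cells, at least 3140.5-fold lower against a floor of 3 reads over the group. Ltf was 6.02-fold lower (14023 to 2328 CPM), Csn1s2a 6.23-fold, Csn2 2.76-fold, the sorting receptor Sort1 5.09-fold, Mtmr9 8.98-fold and the non-coding Gt(ROSA)26Sor 9.30-fold. Lect1 (402-fold), Alox15 (13.96-fold), the stress gene Gadd45g (8.04-fold), Fbn2 (5.64-fold), D8Ertd82e (4.47-fold) and Spon1 (4.29-fold) were higher. Milk protein genes were at least 1.5 times lower in 8 of 9 members (median -1.79, percentile 0), milk lipid genes in 8 of 16 (-0.55, 0.110; Scd1 3.94-fold), prolactin and STAT5 genes in 5 of 8 (-0.67, 0; Stat5b 2.07-fold) and luminal progenitor markers in 6 of 11 (-0.61, 0.160). The progenitor median was under 1.5 times in 3 settings, the lowest -0.45 in well columns 13 to 24, and the prolactin and STAT5 median in 2, at -0.56 with both plates clustered together and -0.57 by the mean of per-cell CPM. MHC genes had a median of 0.80 (percentile 99.91), which was 0.30 in well columns 1 to 12 and 0.42 without possible doublets. Immune cell markers were higher in the same cells (6 of 6 members, median 1.98, percentile 99.2), but their median was -0.45 under the stricter filter. Pan-luminal genes had a median of 0.17 (percentile 80.3), with Krt8 at 709.6 and 802 CPM, Kit at 731 and 819 CPM and Cldn4 2.68-fold higher. Milk and progenitor genes also served to name this class, cluster 6 of the N1ICD-EGFP plate (28 cells) had 7 progenitor markers but 1 secretory marker raised, and the median over all genes was 0.10. Basal markers (median 3.03) and mesenchymal genes (3.03) rested on few cells, with Krt14 read in 0.971% and 2.73% of cells thinned (1.94% and 4.92% unthinned), and the mesenchymal median was -0.61 with both plates clustered together.

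The lower Gt(ROSA)26Sor reads lay at the locus that carries the transgenes of both genotypes (chromosome 6, 113067428 to 113077244, GRCm38). Within the luminal progenitor/secretory-like cells it stood at 105.2 CPM in the control and 11.3 in the N1ICD-EGFP plate (log2 ratio -3.11). The adjacent protein-coding gene Setd5 (113077262 to 113153432), chosen after its values were seen, stood at 297.2 and 68.3 CPM (-2.11). The other 13 genes at 5 CPM or more within 500 kb had ratios from -0.08 to 1.10 with a median of 0.35. Among them Thumpd3, which overlaps Gt(ROSA)26Sor, stood at 46.9 and 71.7 CPM; whether the counting used strand is not given in the sources used here, so reads in the overlap could belong to either gene.

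**Figure D4:**
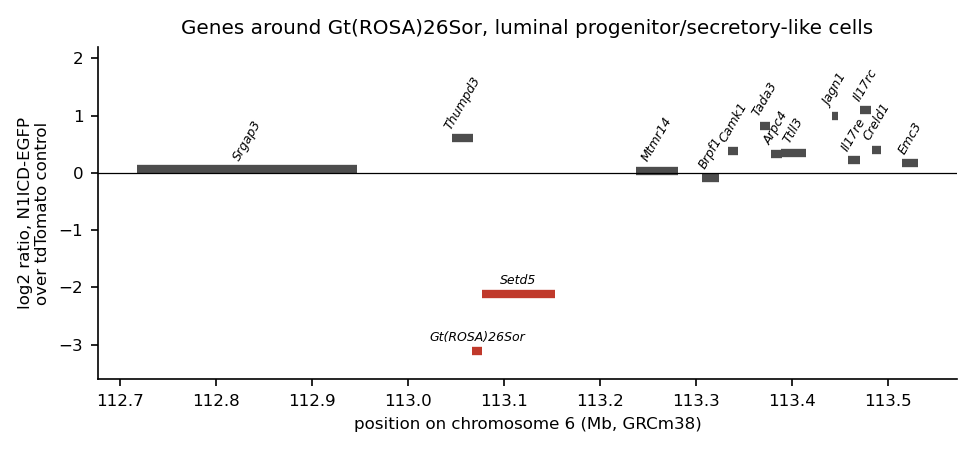
Log2 ratio (N1ICD-EGFP over tdTomato control, luminal progenitor/secretory-like cells) of the genes at 5 CPM or more within 500 kb of Gt(ROSA)26Sor, each drawn as a bar over its position on chromosome 6 (Mb, GRCm38). Gt(ROSA)26Sor (-3.11) and Setd5 (-2.11), in red, lie below the other 13 genes, in grey, which range from -0.08 to 1.10.

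Within the immune-like cells (cluster 4 of the control; clusters 1, 4 and 5 of the N1ICD-EGFP plate; median depths 207726 and 339930 reads), interferon response genes were at least 1.5 times higher in 12 of 14 members (median 1.19, percentile 99.95), with Irf7 at 148.6 and 635 CPM and Bst2 at 102.9 and 495. Immediate early genes were lower in 8 of 17 (median -0.49, percentile 1.56), with Nr4a1 at 1483 and 321.995 CPM. The B cell genes Cd79a and Ms4a1 were 3.44-fold and 7.20-fold higher, the macrophage genes Retnla and F13a1 went from 0 to 8346 and from 1.52 to 748 CPM with Clec12a, Fcrls, Cr2 and Gdpd3 also higher, and the T cell genes Ccl5 (1394 to 0.0587 CPM) and Ctla4 (536 to 0 CPM) were lower, as were Mmp12, Nt5e and H2-M2. Ltf, a luminal gene, was read in 58.3% of the control and 4.17% of the N1ICD-EGFP immune-like cells (87.5% and 22.9% unthinned), which puts luminal RNA in immune-like wells of the control plate. Milk protein genes (-5.58, percentile 0), pan-luminal genes (-3.58, 0) and luminal progenitor markers (-4.29, 0) were accordingly lower in the N1ICD-EGFP immune-like cells. With 24 and 48 cells of several immune types, these values also carry the mix of types.

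Among the named classes found in both plates, Notch1 was highest in the luminal progenitor/secretory-like cells of each plate. It stood at 276.7 CPM there, 47.4 in hormone-sensing luminal-like and 44.2 in immune-like cells of the control plate, and at 279.5, 14.4 and 43.4 CPM in the N1ICD-EGFP plate. Hey1 stood at 609 CPM in luminal progenitor/secretory-like and 6.41 in hormone-sensing luminal-like cells of the control, and at 358.7 CPM in luminal progenitor/secretory-like cells and 0 reads in the 7 hormone-sensing luminal-like cells of the N1ICD-EGFP plate. Hes1 stood at 227.8 and 113.1 CPM in these control classes and at 646 and 117.4 in the N1ICD-EGFP plate. The ligand gene Jag1 was higher in hormone-sensing luminal-like than in luminal progenitor/secretory-like cells of both plates (116.7 and 2.63 CPM in the control, 77.8 and 29.3 in the N1ICD-EGFP plate). eGFP was read in 73 luminal progenitor/secretory-like (39.9%, 32.7 to 47.4), 19 of 45 unnamed (42.2%, 27.7 to 57.8), 1 of 48 immune-like (2.08%, 0.0527 to 11.1) and 0 of 7 hormone-sensing luminal-like cells (0 to 40.96, and up to 42.9% by a floor of 3 counts) of the N1ICD-EGFP plate, at median depths of 352662, 318628, 339930 and 417390 reads. In the control plate the corresponding background shares were 22.8% of luminal progenitor/secretory-like and 6.15% of hormone-sensing luminal-like cells.

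Cells with reads of cell cycle genes were few. At least 2 of Mki67, Top2a and Cdk1 were read in 3 control cells (0.898%, 0.186 to 2.602) and 5 N1ICD-EGFP cells (1.77%, 0.576 to 4.07) after thinning, and in 4 (1.198%) and 8 (2.83%) unthinned. The intervals overlap, but they cover counting error only and their overlap is no test, so nothing on a difference was concluded from these few cells. The 5 N1ICD-EGFP cells all lay in the unnamed cluster of that plate (5 of 45, 11.1%), as did 7 of the 8 unthinned, with 1 in the luminal progenitor/secretory-like class. Of the 3 control cells 1 lay in the unnamed cluster (1 of 32, 3.13%), where Mki67 was read in 18.8% of cells, against 15.6% in that of the N1ICD-EGFP plate. Mki67 stood at 6.95 and 35.3 CPM over all cells but was read in 15 and 14 cells, and its ratio turned round in well columns 13 to 24 (log2 -1.38).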

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

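The settings without immune-like cells, without unnamed clusters and with immune-like cells left out of the denominator, the clustering settings within a class, and the 20% condition on list members were chosen after the results were seen. No paired analysis was possible because the labels link no cell or plate of 1 genotype to 1 of the other. Alternatives for the comparison within immune-like cells were not run.

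Over all cells, the 28 genes of largest ratio kept their direction in all 12 settings, and 27 stayed past 1.5 times, the exception being H2-Eb1 without immune-like cells. The naming rule already required this direction in the mean of per-cell CPM and in the well columns, so these settings could not turn it. A larger pseudocount could not turn it either, and genes picked for large ratios have more room above 1.5 times. Of 53 genes from lists or fixed, 45 kept their direction and 23 stayed past 1.5 times. Without the 20% condition these were 79 and 41 of a larger set, with 29 values turned round. Within luminal progenitor/secretory-like cells (the class below), the 12 genes of largest ratio kept both in 14 settings. For these the naming rule had fixed the direction in the mean of per-cell CPM. Of 48 other genes, 37 kept their direction and 15 stayed past 1.5 times, and without the condition 70 and 30 of a larger set, with 34 values turned round. Of 14 lists with a median past 1.5 times over all cells, 9 kept their direction and 5 stayed past it in 13 settings, and within the class 7 and 4 of 11 in 15 settings.

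The values below lay outside their counting interval or turned round. The cause was not tested. With list members at 1 CPM or more, log2 ratios over all cells were -2.32 for hormone-sensing markers, and within the class 1.10 for Notch target genes and -1.70 for milk protein genes. With at least 100000 reads and 2000 genes, log2 ratios over all cells were 0.27 for Notch1, 0.75 for Notch target genes, -2.30 for hormone-sensing markers and -1.54 for milk protein genes, and within the class 0.65 for Notch target genes and -1.83 for milk protein genes. Here the direction turned round, to -0.47 for adipocyte markers, 0.56 for Pgr within the class, 0.18 for hormone-sensing markers within the class and -0.45 for immune cell markers within the class. Here the shares were 73.5% for luminal progenitor/secretory-like cells (control), 2.79% for immune-like cells (control), 9.84% for immune-like cells (N1ICD-EGFP), 74.7% for wells kept (control) and 50.3% for wells kept (N1ICD-EGFP). With at least 20000 reads and 500 genes, log2 ratios over all cells were 0.15 for Notch1, 0.99 for Notch target genes, -2.45 for hormone-sensing markers and -1.75 for milk protein genes, and within the class 0.88 for Notch target genes and -1.94 for milk protein genes. There the direction turned round, to 1.41 for Mki67 within the class and -0.77 for mesenchymal transition genes within the class. There the shares were 54.9% for luminal progenitor/secretory-like cells (control) and 95.3% for wells kept (control). Without possible doublets, log2 ratios over all cells were 0.011 for Notch1, 0.83 for Notch target genes, -1.97 for hormone-sensing markers and -2.01 for milk protein genes, and within the class -1.83 for milk protein genes. The shares were 67.7% for luminal progenitor/secretory-like cells (control), 10.5% for hormone-sensing luminal-like cells (control), 41.02% for luminal progenitor/secretory-like cells (N1ICD-EGFP), 0% for hormone-sensing luminal-like cells (N1ICD-EGFP), 76.6% for wells kept (control) and 66.7% for wells kept (N1ICD-EGFP). Unnamed were 40.6% of the N1ICD-EGFP cells in this setting, against 15.9% as reported. The setting leaves out cells with many genes, and hormone-sensing luminal-like cells had the most. By the mean of per-cell CPM, log2 ratios over all cells were 0.061 for Notch1, 0.86 for Notch target genes, -2.43 for hormone-sensing markers and -1.89 for milk protein genes, and within the class 0.79 for Notch target genes and -1.83 for milk protein genes. The direction turned round, to 0.20 for Mki67 within the class. Thinned to 50000 reads before summing, log2 ratios over all cells were 0.073 for Notch1, 0.89 for Notch target genes and -1.89 for milk protein genes, and within the class 0.85 for Notch target genes and -1.83 for milk protein genes. Here the direction turned round, to -0.37 for adipocyte markers and 0.054 for Mki67 within the class. With median-ratio scaling, log2 ratios over all cells were 0.98 for Notch target genes and -1.66 for milk protein genes, and within the class 0.62 for Notch target genes and -1.88 for milk protein genes.

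With a total without milk proteins and the 20 most abundant genes, log2 ratios over all cells were 0.13 for Notch1, 0.96 for Notch target genes and -1.81 for milk protein genes, and within the class 0.63 for Notch target genes and -1.88 for milk protein genes. In well columns 1 to 12, log2 ratios over all cells were 0.24 for Notch1, 1.28 for Notch target genes and -1.76 for milk protein genes, and within the class 1.17 for Notch target genes and -1.94 for milk protein genes. There the direction turned round, to -0.66 for adipocyte markers and -0.72 for Cd74 within the class. Here the shares were 56% for luminal progenitor/secretory-like cells (control). In well columns 13 to 24, log2 ratios over all cells were 0.14 for Notch1, 0.67 for Notch target genes, -2.40 for hormone-sensing markers and -1.76 for milk protein genes, and within the class 0.68 for Notch target genes and -1.77 for milk protein genes. The direction turned round, to -1.38 for Mki67, 0.29 for basal and myoepithelial markers, -0.22 for G2 and M phase genes and -2.17 for red blood cell genes within the class. There the shares were 67.9% for luminal progenitor/secretory-like cells (control) and 0.719% for hormone-sensing luminal-like cells (N1ICD-EGFP). With a pseudocount of 5 CPM, log2 ratios over all cells were 0.79 for Notch target genes and -2.32 for hormone-sensing markers, and within the class -1.69 for milk protein genes. Without immune-like cells, log2 ratios over all cells were 0.34 for Notch1, 1.16 for Notch target genes, -2.36 for hormone-sensing markers and -1.56 for milk protein genes. Here the direction turned round, to -0.082 for interferon response genes. Without cells of unnamed clusters, log2 ratios over all cells were 0.86 for Notch target genes and -1.50 for milk protein genes. There the direction turned round, to -0.99 for Krt14, -1.23 for Mki67 and -0.62 for fibroblast markers. At Leiden resolution 0.5, log2 ratios within the class were 0.68 for Notch target genes and -1.82 for milk protein genes. The shares were 17.4% for immune-like cells (control). With both plates clustered together, log2 ratios within the class were 0.85 for Notch target genes and -1.61 for milk protein genes. The direction turned round, to -0.61 for mesenchymal transition genes within the class. Here the shares were 48.1% for luminal progenitor/secretory-like cells (N1ICD-EGFP) and 30.4% for unnamed cells (N1ICD-EGFP), the latter against 15.9% as reported. Clustered on the fixed markers, log2 ratios within the class were -1.73 for milk protein genes. Here the direction turned round, to 0.98 for Mki67 within the class, 0.23 for Pgr within the class and 0.23 for hormone-sensing markers within the class. There the shares were 71.6% for luminal progenitor/secretory-like cells (control) and 9.89% for hormone-sensing luminal-like cells (N1ICD-EGFP). With immune-like cells left out of the denominator, shares were 77.9% for luminal progenitor/secretory-like cells (N1ICD-EGFP).

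Depth limits which genes are read: thinned to 50000 reads, median genes per cell were 3107.5 and 2088, against 3598 and 2482. Of unchanged simulated genes 33.6% passed 1.5 times at 5 to 20 CPM and 8.90% above; the part of depth in this was not tested.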

Other observations

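All tests below were chosen after the results were seen, except that of the 500 kb neighbourhood. The genes named for the unnamed cluster and Setd5 were also chosen after their values were seen.

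The unnamed cluster of the N1ICD-EGFP plate (45 cells) held collagen VI genes, with Col6a1 at 1368 and Col6a2 at 1062 CPM against 25.9 and 13.2 CPM in the luminal progenitor/secretory-like cells of that plate. The retinol transporter gene Stra6 stood at 408 against 0.644 CPM, Nkd2, an inhibitor of Wnt signalling, at 1466 against 73.03 CPM, the transcription factor gene Tbx3 at 171.7 against 8.94 CPM and the basal keratin gene Krt14 at 949.6 against 30.4 CPM. Tbx3 is among the fixed hormone-sensing markers. By the naming rule the cluster had 1 hormone-sensing, 2 luminal progenitor and 1 basal marker raised. Nkd2 was read in 68.9% and 6.01% of these cells. These genes lead the cluster and so partly define it, and since it came from 1 plate it cannot be told from that plate.

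The smaller share of hormone-sensing luminal-like cells in the N1ICD-EGFP plate was weighed against technical explanations. Fewer detected genes per cell were set against the markers. After thinning, the share of cells with a read of 11 hormone-sensing markers had a median log2 ratio of -1.77. This was at percentile 0 of matched random lists, whose middle 95% ran from -0.67 to -0.26. The marker shares thus fell more than those of genes at like expression. But these markers also name the class, so fewer such cells means fewer marker reads, and this explanation stays open. Dilution by other cells is argued against, under the reported naming, by the share among named luminal-like and basal-like cells alone. That share was 3.68% (7 cells, 1.49 to 7.44) against 23.4% (65 cells, 18.5 to 28.8). Clustered on the fixed markers, the N1ICD-EGFP plate had 28 hormone-sensing luminal-like and 23 unnamed cells, against 7 and 45 as reported. Unnamed cells that belong to this class are therefore not excluded. A sorting gate that differs between the reporter colours cannot be told apart from genotype, as the 7 cells of this class come from 1 plate with 1 colour. An effect of active Notch1 on this lineage also stays open, untested, and the share was 9.89% when cells were clustered on the fixed markers.

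The larger share of immune-like cells in the N1ICD-EGFP plate was lost at the lowest clustering resolution. There the control share was 17.4% and the control plate kept no unnamed cluster. The larger share was kept in the other settings that count these cells, such as 15.97% against 8.57% in well columns 1 to 12. Immune-like cells that express the reporter as luminal cells do are argued against by eGFP reads in 2.08% (0.0527 to 11.1) of them, against 39.9% (32.7 to 47.4) of luminal progenitor/secretory-like cells. Luminal cells sorted into the same wells of this plate are argued against by Krt8 reads after thinning in 2.08% (0.0527 to 11.1) of them, against 93.4%. Unthinned, Krt8 was read in 14.6% of these immune-like cells, against 97.3% of luminal progenitor/secretory-like cells, and Krt19 in 37.5% of them. Small amounts of luminal RNA in these wells are therefore not excluded. In the control plate Krt8 was read in 25% (9.77 to 46.7) and Ltf in 58.3% of immune-like cells, so mixed wells there, which could lower the control share, stay open and were not tested. Gating and tissue differences between the plates stay open, and no biological explanation was tested.

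Lower Gt(ROSA)26Sor and Setd5 reads in the N1ICD-EGFP plate were found within luminal progenitor/secretory-like cells, so low ratios there are no test by themselves, and other classes or other genes were used. A different mix of the named classes does not apply to ratios within 1 of them, but a different mix of cells within this class stays open: the share of cells with a Setd5 read lay below that of the control in 1 of 2 classes, the hormone-sensing luminal-like one (42.9%, 9.899 to 81.6, against 95.4%, 87.1 to 99.04; unthinned 57.1% against 96.9%), while the intervals overlapped in immune-like cells (27.1%, 15.3 to 41.8, against 50%, 29.1 to 70.9). With fewer detected genes per cell, genes of like expression were not lower in general. The 500 genes nearest in expression to each had median log2 ratios of 0.14 (middle 95% -0.997 to 1.27) and 0.14 (-0.82 to 1.08), against -3.11 and -2.11. Their shares of cells fell, however (medians -0.38 and -0.34), and Setd5 lay at percentile 34.6 of such genes within immune-like cells. Gt(ROSA)26Sor was picked for its low ratio and Setd5 after its values were seen, so their place below such genes decides nothing on this cause. Lower expression of the whole neighbourhood is argued against by a median of 0.35 for the other 13 genes within 500 kb. A difference between the transgene insertions at this locus, the allele dose and the use of strand in counting were not tested and stay open. The labels hold the word homo for both groups, and its meaning is not given in the sources used here.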
